A study of Mus musculus with 4 samples.

How the data were processed

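Exome libraries of 4 mouse tumour cell lines were compared through the variant lists made from them: YUMM 1.1, YUMM 1.3, UV YUMM 1.1-9 and MB49. Each line was sequenced as 1 library, so no group has a replicate. Per the labels' protocols, genomic DNA was captured with an Agilent SureSelect Mouse All Exon kit and sequenced on an Illumina NextSeq550 as paired reads of 151 bases, to a stated mean depth of 80X. The submitters' processing notes name FastQC, BWA 0.7.5a, GATK, Picard and SAMtools and the genome build mm10, with no role or order. The variant caller, its filters and its thresholds are not given in the sources used here. Each list is 1 table headed with the name of its line. No sample label reads MB49; the table headed MB49 was taken for the sample labelled 49XC-49 by elimination, because the other 3 headings match the other 3 labels.

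Per the file headers, each row gives a position, the new base, a predicted consequence, the codon and amino acid change, a SIFT class for many missense changes, and the number of reads with the reference and the alternative base. These deposited read counts are whole numbers and are not normalized. The UV YUMM 1.1-9 table is of another kind than the rest: per its header it holds additional mutations relative to YUMM 1.1, and it also gives the read counts of YUMM 1.1 at each site. The 3 single-line tables hold no site under 5 alternative reads or under an allele fraction of 10.0%, while the UV YUMM 1.1-9 table goes down to 3 alternative reads and 3.62%. List sizes were therefore also set side by side after a common floor of 5 alternative reads and 10% was applied to every list, a setting chosen after the data were seen. All listed changes were single-base changes in coding sequence.

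Rows with the same position and new base were counted once, which removed 1 row of YUMM 1.1 and 5 rows of UV YUMM 1.1-9. Substitution classes were written from the pyrimidine of the changed base pair and taken from the codon and new-base columns. The neighbouring base was known only where it lay within the same codon, since no genome sequence was used here. In the UV YUMM 1.1-9 table, 32 rows carry reference and alternative bases that belong to a partner row of the same gene. Exchanging the columns within each of the 16 gene pairs restored both rows, and 5 of these pairs lie more than 2 bases apart, so their read counts may be exchanged as well. In 3 rows over 2 tables the gene symbol had been turned into a calendar date; these genes are unnamed here. Gene symbols were matched to the RefSeq protein-coding genes of GRCm38, the assembly also called mm10, through current symbols and unambiguous synonyms. Of the listed symbols, 328 of 345 matched for YUMM 1.1, 591 of 610 for UV YUMM 1.1-9, 153 of 170 for YUMM 1.3 and 593 of 618 for MB49. The background held 21900 protein-coding genes. Multigene families were told by gene symbol alone. Counted were symbols that begin with Olfr, Vmn, Zfp, Muc, Krtap, Pramel, Speer, Mup, H2-, Skint, Ugt or Cyp. Symbols of Gm and a digit, and those that end in Rik, were counted too, whether or not the gene has related copies. LOC symbols were not counted, so removing families is a filter on names.

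The allele fraction is the number of alternative reads over the sum of both read counts. Counts of variants were given exact Poisson intervals and shares exact (Clopper-Pearson) intervals, both at 95%, and differences of shares Newcombe intervals. Totals of 2 lists were compared by an exact binomial test and shares by Fisher's exact test, two-sided. Gene overlaps were tested by a one-sided Fisher's exact test. Median allele fractions were compared by a two-sided permutation test with 100000 resamples. P values were adjusted by the Benjamini-Hochberg method over the 6 pairs of lines, over the 36 combinations of class and pair, or over the 36 combinations of gene list and line, with a threshold of 0.05. Intervals and tests cover counting error only. They compare these libraries and not conditions, and variants of 1 library are not independent replicates. Read counts without molecular identifiers are not independent molecules.

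The 9 gene lists, the main tests and most alternatives were fixed before the data were examined. Chosen after the data were seen were the tests of stop gains, of SIFT classes, of the bases beside T>A and C>G changes, of coding strand, of tandem changes and of chromosomes, the correlation of allele fractions at shared sites and the site-by-site comparison of reads with YUMM 1.1. The lists cover autophagy, DNA repair, melanoma genes, bladder cancer genes, antigen presentation and interferon, chromatin regulators, receptor kinases with PI3K signalling, pigment and melanocyte genes, and very long genes, the last as a comparison for gene size. The genes named are those of the lists other than the long genes with a protein-changing variant (up to 30), the 5 genes per line with the most variants with ties taken by symbol, up to 10 genes with a protein change in all lines compared, and the 10 genes with the highest allele fraction among those with a stop gain in UV YUMM 1.1-9 and no variant in the other lists. Some genes that this rule takes are not reported here. No gene list was weighted by coding length, which the gene table used here does not hold. Alternatives were a depth of at least 20 reads, an allele fraction of at least 20%, removal of sites listed in 3 lines, every row as listed, neighbouring changes within 2 bases counted as 1 event, removal of multigene families, missense and nonsense changes only, another gene background, other definitions of a shared site and, added later, the common floor and the base columns in place of the codons.

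The functions were tested on simulated lists of the sizes of UV YUMM 1.1-9 and YUMM 1.1, drawn 100 times. With C>T shares set to 40% and 20%, the recovered mean shares were 40.1% and 20.2%, and the test passed its threshold in all 100 draws. With equal shares it passed in 6 of 100. A coding-strand share of T changes set to 60% in the larger list and to an even split in the smaller was called in 57 of 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.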

Results

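Coding variants were listed for 4 mouse tumour cell lines, with 1 exome library per line and no replicates. YUMM 1.1 and YUMM 1.3 are melanoma lines from genetically engineered mice, and UV YUMM 1.1-9 is set against YUMM 1.1, taken here as its parent, by the heading of its table. MB49 is a bladder carcinoma line obtained by carcinogen treatment. The series title concerns autophagy in tumours with a high mutational burden. Median read depth at the listed sites was 70.0 in YUMM 1.1 (interquartile range 43.0 to 147), 45.0 in UV YUMM 1.1-9 (32.0 to 61.0), 107 in YUMM 1.3 (50 to 249) and 59.0 in MB49 (38.0 to 106). The summed read count at listed sites was 63899, 34839, 48577 and 72270 in the same order.

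The first comparison asked how many coding variants each list held. MB49 had the longest list, with 707 distinct variants (exact Poisson 95% interval 656 to 761), of which 539 changed the protein. UV YUMM 1.1-9 had 653 variants beyond those of its parent (604 to 705), and 433 of them changed the protein. YUMM 1.1 had 428 (388 to 471) with 299 protein-changing, and YUMM 1.3 had 225 (197 to 256) with 168 protein-changing. Variants found in no other list numbered 320 in YUMM 1.1, 120 in YUMM 1.3, 635 in MB49 and all 653 in UV YUMM 1.1-9. For UV YUMM 1.1-9 this follows in part from how its list was made. The ratio of UV YUMM 1.1-9 to YUMM 1.1 was 1.53 for all variants (95% interval 1.35 to 1.73, exact binomial test, adjusted p = 9.69e-12) and 1.45 for protein-changing variants (1.25 to 1.68, adjusted p = 9.92e-07). For all variants the ratio of UV YUMM 1.1-9 to MB49 was 0.924 (0.829 to 1.03, exact test, adjusted p = 0.151), and for protein-changing variants it was 0.803 (0.706 to 0.913, adjusted p = 0.000749). The UV YUMM 1.1-9 list holds only variants additional to YUMM 1.1, so these ratios compare lists and not all variants carried by each line. The ratio of UV YUMM 1.1-9 to its parent depended on which variants were counted: with the common floor of 5 alternative reads and 10%, its list held 376 variants against 428 for YUMM 1.1 (exact test, adjusted p = 0.0720; 2.86e-23 to 0.0720 over the alternatives), and at allele fractions of at least 20% it held 90 against 278.

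Truncating changes made up the largest share in the list of UV YUMM 1.1-9. Stop gains made up 37 of its 653 variants, or 5.67% (exact interval 4.02 to 7.73), against 6 of 428 in YUMM 1.1, or 1.40% (Fisher's exact test, adjusted p = 0.00207), and the difference also passed the threshold against YUMM 1.3 (1.78%, adjusted p = 0.0467) and MB49 (3.11%, adjusted p = 0.0467). Among missense changes with a SIFT class, 56.9% were called deleterious in UV YUMM 1.1-9 and 55.3% in MB49, against 43.2% in YUMM 1.1 and 44.2% in YUMM 1.3. The difference between UV YUMM 1.1-9 and YUMM 1.1 was 13.7 percentage points (5.72 to 21.5, exact test, adjusted p = 0.00494). Neither comparison was repeated with the common floor, on variants found in no other list or with neighbouring changes joined. How far the unlike make-up of the lists contributes was therefore not examined. Each base was annotated alone, and pairs within 2 bases numbered 26 in UV YUMM 1.1-9, 2 in YUMM 1.1, 1 in YUMM 1.3 and 15 in MB49. Y24N and Y24* in 2700062C07Rik, with 3 of 25 and 3 of 24 reads, share 1 codon. If carried together, they would give lysine and no stop. Of the 37 stop gains, 34 lay in genes with no variant in the other 3 lists, and 14 came from C>T changes. The highest allele fraction was that of Q772* in Ntrk2, which encodes the neurotrophin receptor TrkB, at 13:59128201 with 5 of 14 reads, or 35.7% (exact interval 12.8 to 64.9). R745* in Limch1 had 8 of 32 reads, K2087* in Tnxb, an extracellular matrix tenascin, 13 of 56, and K432* in Stau1, an RNA-binding protein, 13 of 65. R145* in the odorant receptor gene Olfr1325, S400* in 6030458C11Rik, E198* in Gm2832, K207* in Pi16, K1278* in Cfap65 and Q851* in Csmd3 had allele fractions from 21.7% down to 16.1%. In YUMM 1.1 the alternative base was seen in 1 read each at the Tnxb and Gm2832 sites and in none at the others of these 10.

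Ultraviolet light is known to leave C>T changes where pyrimidines lie side by side, so base changes were compared between UV YUMM 1.1-9 and its parent. C>T was the leading class in UV YUMM 1.1-9, with 283 of 653 variants, or 43.3% (exact interval 39.5 to 47.2). In YUMM 1.1 it made up 93 of 428, or 21.7% (17.9 to 25.9). The difference was 21.6 percentage points (16.0 to 26.9, Fisher's exact test, adjusted p = 1.09e-12). The C>T share was 30.2% in YUMM 1.3 and 32.4% in MB49, both below UV YUMM 1.1-9 (exact test, adjusted p = 0.000769 and 0.000101). At allele fractions of at least 20% the differences to YUMM 1.3 and MB49 were 11.6 and 7.77 percentage points, on 90 variants of UV YUMM 1.1-9, and no longer passed the threshold (exact test, adjusted p = 0.159 and 0.183, the highest among the alternatives; the lowest were 0.000680 and 5.77e-05).

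**Figure D1:**
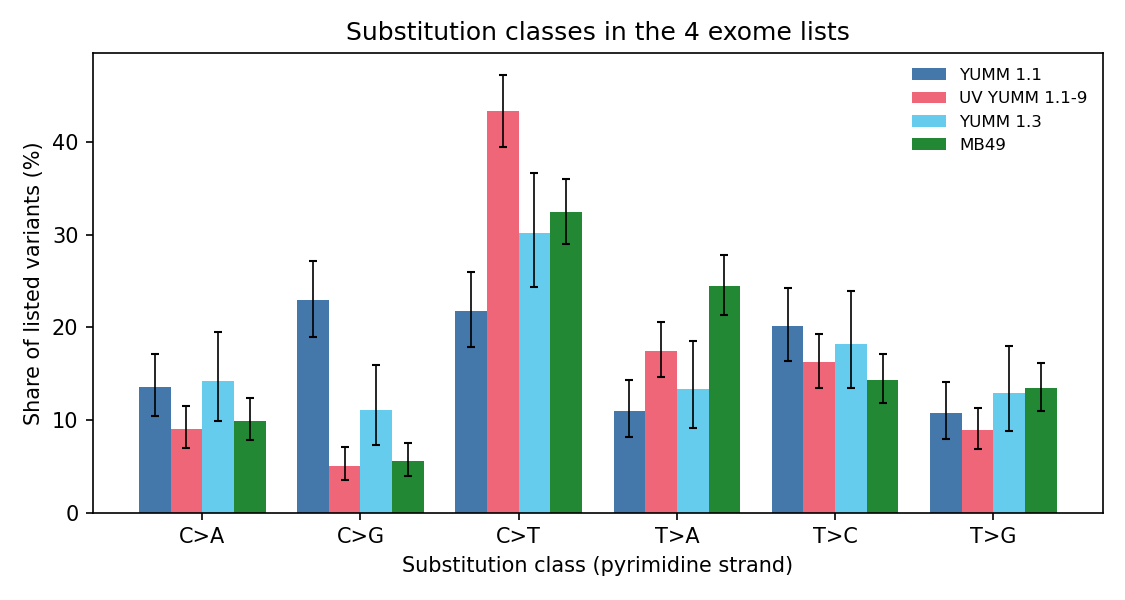
Share of listed variants in each of the 6 substitution classes, in percent, for the 4 cell lines. Bars are shares of all distinct variants of 1 library and error bars are exact 95% intervals; C>T reaches 43.3% in UV YUMM 1.1-9, C>G 22.9% in YUMM 1.1 and T>A 24.5% in MB49.

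The sequence before the changed base separated the lists further. Where the codon showed the base 5' of the changed C, it was a pyrimidine in 160 of 182 C>T changes of UV YUMM 1.1-9, or 87.9% (82.3 to 92.3), and in 26 of 65 of YUMM 1.1, or 40% (28.0 to 52.9), a difference of 47.9 percentage points (34.6 to 59.6, exact test, adjusted p = 1.53e-12). The share was 43.9% in YUMM 1.3 and 66.7% in MB49, both below UV YUMM 1.1-9 (Fisher's exact test, adjusted p = 2.51e-08 and 4.43e-06). The difference to MB49 did not pass at allele fractions of at least 20% (exact test, adjusted p = 0.412; 4.06e-06 to 0.412 over the alternatives). Among unchanged C bases in the same codons of all lists it was 54.6% (51.9 to 57.3). T preceded the changed C in 112 of the 182 changes of UV YUMM 1.1-9, or 61.5% (54.1 to 68.6), and in 18.5% of those of YUMM 1.1. In MB49 it did so in 46.9% (39.0 to 54.9) and in YUMM 1.3 in 14.6%. T>A changes of UV YUMM 1.1-9 also followed a pyrimidine more often, in 54 of 71, or 76.1%, against 44.1% in YUMM 1.1 (exact test, adjusted p = 0.00651). Both neighbours were known only at the middle codon position; there 51 of 52 C>T changes of UV YUMM 1.1-9 lay in a dipyrimidine, or 98.1%, against 23 of 27 in YUMM 1.1 (exact test, adjusted p = 0.0983). Restricting every list to variants found in no other list gave a C>T difference of 25.8 percentage points between UV YUMM 1.1-9 and YUMM 1.1 (19.9 to 31.2, exact test, adjusted p = 1.76e-15) and 38.1% of C>T after a pyrimidine in YUMM 1.1. Tandem CC>TT changes numbered 3 in UV YUMM 1.1-9 (exact Poisson interval 0.619 to 8.77), in Celf1, Mup9 and Aplf, 4 in MB49 (1.09 to 10.2), in Rbck1, Bckdha, Olfr697 and Olfr887, and 0 in the YUMM 1.1 and YUMM 1.3 lists; these genes were singled out after the values were seen.

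**Figure D2:**
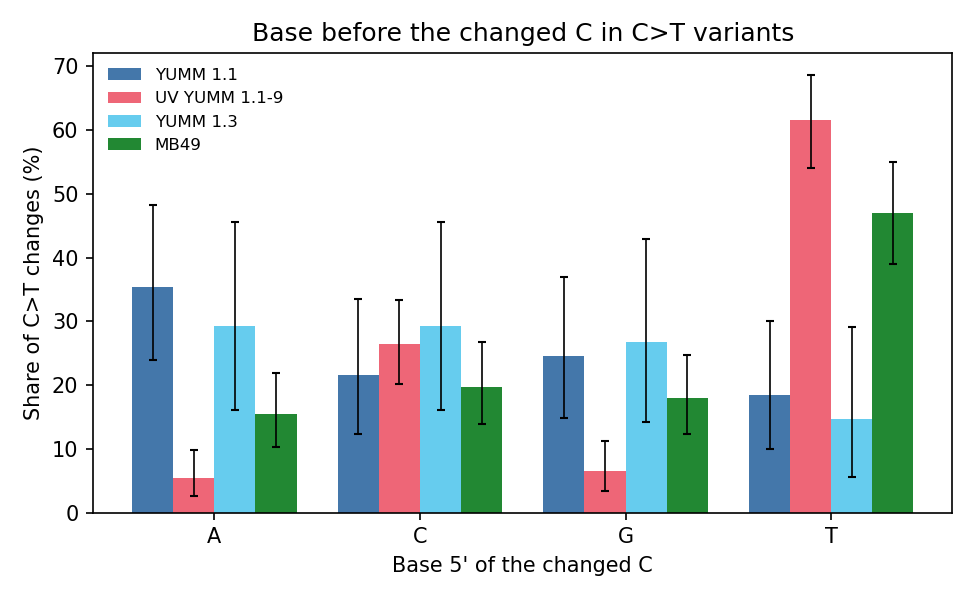
Base 5' of the changed C among C>T variants, as percent of those whose codon shows it, for the 4 cell lines (n = 65, 182, 41 and 162 in the order of the legend). Error bars are exact 95% intervals. T precedes the changed C in 61.5% of the UV YUMM 1.1-9 changes, 46.9% of the MB49, 18.5% of the YUMM 1.1 and 14.6% of the YUMM 1.3 changes.

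The other lines had spectra of their own, and 17 of the 36 class and pair tests passed the threshold. In MB49, T>A made up 173 of 707 variants, or 24.5% (21.3 to 27.8), against 11% in YUMM 1.1 (exact test, adjusted p = 1.07e-07) and 17.5% in UV YUMM 1.1-9 (adjusted p = 0.00629). G followed the changed T in 60 of 119 T>A changes of MB49, or 50.4% (41.1 to 59.7), compared with 6 of 74, or 8.11% (3.03 to 16.8), in UV YUMM 1.1-9 (exact test, adjusted p = 2.19e-09) and 7 of 31 in YUMM 1.1 (adjusted p = 0.0232). The share of 27.3% in YUMM 1.3 did not differ from MB49 past the threshold (exact test, adjusted p = 0.0746). Taking all T changes of MB49, T lay on the coding strand in 142 of 369, or 38.5% (33.5 to 43.7), while in UV YUMM 1.1-9 it did so in 164 of 278, or 59.0% (53.0 to 64.8), a difference of 20.5 percentage points (12.8 to 27.9, exact test, adjusted p = 1.95e-06). The share was 49.7% in YUMM 1.1 and 53.0% in YUMM 1.3, and neither differed from UV YUMM 1.1-9 past the threshold (9.27 percentage points, -0.0562 to 18.4, exact test, adjusted p = 0.0817 for YUMM 1.1, and adjusted p = 0.415 for YUMM 1.3). Both lay above MB49, by 11.2 and 14.5 percentage points (exact test, adjusted p = 0.0260 for each). For C>T changes no difference was detected, with C on the coding strand in 53.2% in UV YUMM 1.1-9 and 53.7% in MB49 (difference -0.520 percentage points, -9.13 to 8.13). In YUMM 1.1, C>G made up 98 of 428 variants, or 22.9% (19.0 to 27.2), above the 5.52% of MB49 (exact test, adjusted p = 2.93e-16), the 5.05% of UV YUMM 1.1-9 (adjusted p = 1.76e-16) and the 11.1% of YUMM 1.3 (adjusted p = 0.00108). Median depth at these C>G sites was 48.0 reads, against 79.5 at the other sites of that list.

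**Figure D3:**
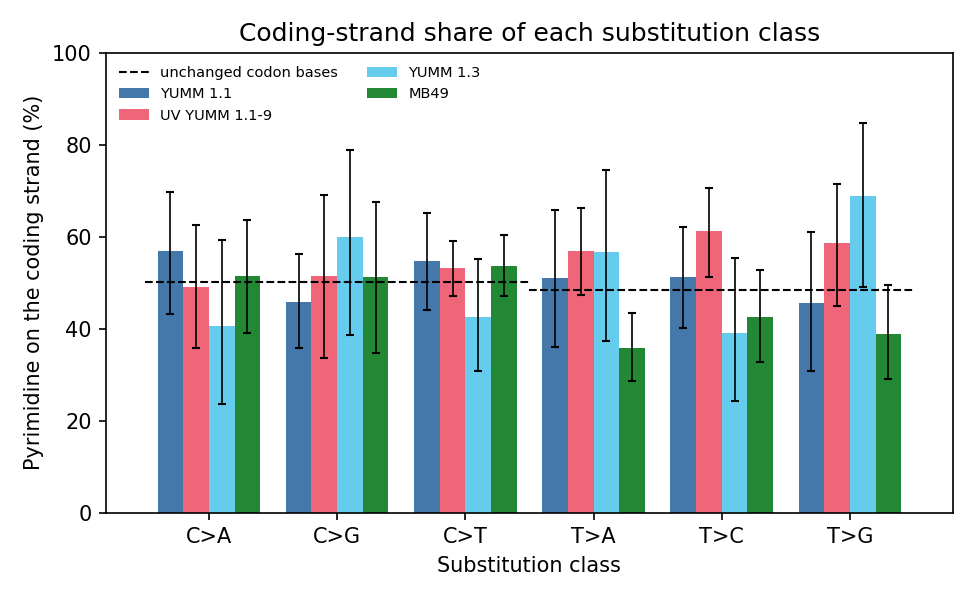
Share of changes whose pyrimidine lies on the coding strand, in percent, by substitution class and cell line, with exact 95% intervals. Dashed lines give the share of C among C and G (50.1%) and of T among A and T (48.5%) in unchanged codon bases of all lists; all T changes as 1 group lie at 38.5% in MB49 and 59.0% in UV YUMM 1.1-9.

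The allele fraction was lowest in UV YUMM 1.1-9. Its median was 13.5% (interquartile range 10 to 16.9), against 24.9% (16.7 to 33.3) in YUMM 1.1, 19.4% (12.9 to 38.8) in YUMM 1.3 and 45.7% (34.8 to 53.7) in MB49. The median fell by 11.4 percentage points from YUMM 1.1 to UV YUMM 1.1-9 (permutation test over variants, adjusted p = 2.4e-05, from the smallest p that the resamples can give). The highest allele fractions were 72.5%, 74.4% and 73.7% in YUMM 1.1, YUMM 1.3 and MB49 and 41.2% in UV YUMM 1.1-9, so the lists hold no site at which nearly all reads carried the new base. An allele fraction above 50% was found for 242 MB49 variants, or 34.2% (30.7 to 37.9), for 4.91% of YUMM 1.1, for 6.67% of YUMM 1.3 and for 0 of 653 in UV YUMM 1.1-9. At the UV YUMM 1.1-9 sites, YUMM 1.1 had no alternative read at 585 and 1 alternative read at 68. Summed over sites, alternative reads were 68 of 40644 in YUMM 1.1, or 0.167% (0.130 to 0.212), and 4554 of 34839 in UV YUMM 1.1-9, or 13.1% (12.7 to 13.4), where the sites had been selected for that difference. A count of 0 in YUMM 1.1 allowed a share of up to 6.12% at the median site. Taken site by site, the read counts of the 2 lines differed at 418 of 653 sites (Fisher's exact test, adjusted over sites), and no difference was detected at the others. The sites had been selected for this same contrast, so this count is no separate evidence that the variants are new.

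**Figure D4:**
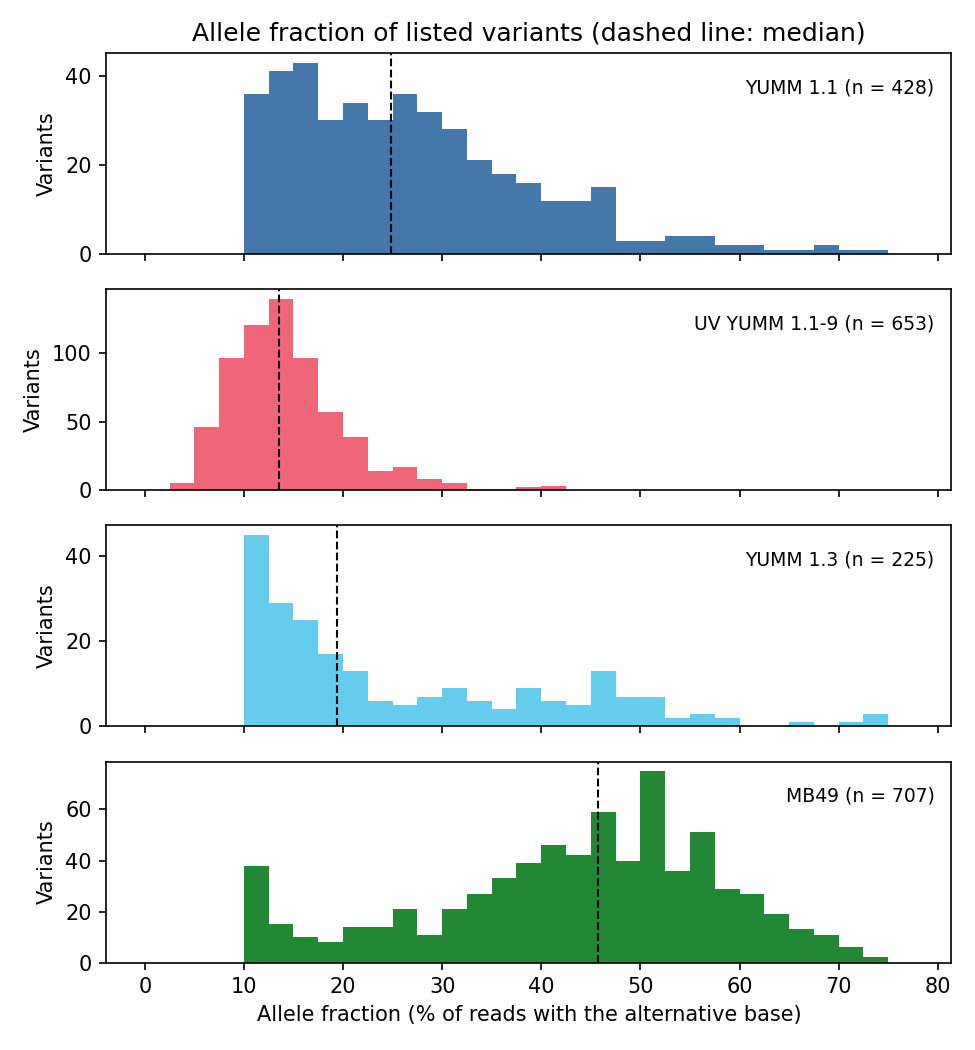
Number of variants by allele fraction, in percent of reads with the alternative base, for the 4 cell lines in bins of equal width. Dashed lines mark the medians of 24.9%, 13.5%, 19.4% and 45.7% from top to bottom.

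Sharing of sites was compared next, since UV YUMM 1.1-9 is set against YUMM 1.1 by name. UV YUMM 1.1-9 shared 0 sites with any list. For YUMM 1.1 this follows from how the list was made. For YUMM 1.3 and MB49 it follows in part, since a variant of YUMM 1.1 is left out of that list. Of the 61 sites that YUMM 1.3 and MB49 share, 53 are in the YUMM 1.1 list as well. YUMM 1.1 and YUMM 1.3 had 97 sites in common, or 43.1% of the YUMM 1.3 list (36.5 to 49.9). MB49 shared 64 sites with YUMM 1.1 and 61 with YUMM 1.3, and 53 sites were in all 3 lists. Of these 53 sites, 34 lay in multigene families as told by gene symbol, or 64.2% (49.8 to 76.9), against 18.9% of the sites found in 1 list (Fisher's exact test, p = 1.78e-12). Another 8 of the 53 lay in genes with LOC symbols, which were not counted as families. At the shared sites the allele fractions of 2 lines were close: across the 97 sites of YUMM 1.1 and YUMM 1.3, Pearson's r was 0.877 and Spearman's rho 0.895, each with a permutation p of 1e-05, the smallest that the resamples can give (adjusted p = 1e-05 over 3 pairs of lines; r = 0.884 without the 2 sites farthest from the median). For YUMM 1.1 and MB49 r was 0.841 and rho 0.878, and for YUMM 1.3 and MB49 r was 0.734 and rho 0.805, with the same permutation p. Sites are not independent replicates.

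Genes were shared beyond the overlap of independent lists in 5 of 6 pairs. YUMM 1.1 and YUMM 1.3 shared 55 genes where 2.28 would be shared by independent lists (one-sided Fisher's exact test, adjusted p = 9.79e-61), and UV YUMM 1.1-9 shared 30 with MB49 where 15.9 would be (adjusted p = 0.00111) and 15 with YUMM 1.1 where 8.78 would be (adjusted p = 0.0380). UV YUMM 1.1-9 and YUMM 1.3 shared 8 against 4.11 (exact test, adjusted p = 0.0547), and this pair passed without multigene families and without sites in 3 lists (adjusted p = 0.00952 and 0.0273; 0.00952 to 1 over the alternatives). Without multigene families the excess of YUMM 1.1 and YUMM 1.3 over independent lists fell from 52.7 to 17.9 genes, that of YUMM 1.1 and MB49 from 44.1 to 17.0 and that of YUMM 1.3 and MB49 from 36.9 to 9.94. Without sites in 3 lists it was 32.1, 19.97 and 12.5 genes in the same order, and all of these still passed. With only the genes of any list as background, the excess of YUMM 1.1 and YUMM 1.3 alone passed, and that of the other 5 pairs turned negative (exact test, adjusted p = 1), which follows from keeping only listed genes. Genes differ in length, so chance overlap lies above these values, and at allele fractions of at least 20% the overlaps of UV YUMM 1.1-9 with YUMM 1.1 and MB49 did not pass the threshold. Flg, which encodes the skin barrier protein filaggrin, carried a protein change in all 4 lists, and 33 genes did so in the 3 single-line lists. By symbol these begin with 4931408C20Rik, C130026I21Rik, C87414, Cdh11, Eppk1, Flg, Gm10220, Gm10354, Gm13154 and Gm13212. D29G in Gm10354 was listed in YUMM 1.1, YUMM 1.3 and MB49 with allele fractions of 38.9%, 38.8% and 40.5%. W43C and C46W in Gm10220, I39M and Q174R in Gm13154, C58R and E161A in Gm13212, Q268* in C87414 and V147D and R137K in Cdh11, a cadherin, were also in all 3.

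The genes with the most variants differed in part between lines. Gm15433 was among them in YUMM 1.1, YUMM 1.3 and MB49, and LOC100038947 in YUMM 1.1 and YUMM 1.3, in part through the same sites. In YUMM 1.1 Itga6, the integrin alpha 6 gene (2:71786886-71858427), carried 12 variants, 8 of them protein-changing, where the next gene, Zscan4c, a gene of early embryos, carried 5. The Itga6 variants spanned 29304 bases with allele fractions from 13.7% to 30.4% and depths from 38 to 168, and none was listed in another line. Gm15433, LOC100038947 and Cdh11 followed with 4 each. In UV YUMM 1.1-9 no gene had over 3: Myh6, a cardiac myosin, Dnah9, an axonemal dynein, and Ttn, the giant muscle protein titin, had 3 each, followed by 2700062C07Rik and 4930444G20Rik with 2. The changes of 2700062C07Rik lie in 1 codon and may be 1 event. Ttn carried E25435K, K11292R and E559K. The read counts of Dnah9 E507K and the synonymous Dnah9 change at 11:66072744 may be exchanged with each other, and so may those of the 4930444G20Rik variants. In MB49 Mroh2a had 5 variants, and Flg, Fsip2, Gm15433 and Hjurp had 4 each; Fsip2 carried R2818C, S5838C, K6426I and S6554P at allele fractions from 41.7% to 51.3%. In YUMM 1.3 C130026I21Rik and LOC100038947 had 5, and Gm13212, Gm15433 and Gm21190 had 4.

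In the fixed gene lists, 21 genes other than the very long ones carried 23 protein-changing variants. Of 46 autophagy genes, 36 antigen presentation and interferon genes and 15 pigment genes, 0 had a protein-changing variant in the lists used here (Fisher's exact test against all other genes, adjusted p = 0.261, 0.336 and 1 with the 4 lines pooled). For chromatin regulators, 8 of 43 carried one in at least 1 line, or 18.6%, against 5.12% of other genes (exact test, adjusted p = 0.00630), and 5 did at allele fractions of at least 20%. In YUMM 1.3 the count was 4 of 43, or 9.30% against 0.544% (exact test, adjusted p = 0.00107, and 0.000395 adjusted over the list alone): Dnmt1, the maintenance DNA methyltransferase, Kmt2b, a histone H3 methyltransferase, Ncor1, a nuclear receptor corepressor, and Smarca4, the BRG1 ATPase. Dnmt1 P1140A had 26 of 37 reads, or 70.3% (53.0 to 84.1), while Kmt2b F1223C, Smarca4 E1557G and Ncor1 T2112A lay at 15.6%, 12.8% and 17.8%, and at allele fractions of at least 20% the difference no longer passed (exact test, adjusted p = 0.509; 0.000209 to 0.509 over the alternatives). Many of these genes are long, and the very long genes had higher shares in YUMM 1.1 (5 of 43), UV YUMM 1.1-9 (9 of 43) and MB49 (10 of 43) (Fisher's exact test, adjusted p = 0.00107, 1.29e-06 and 6.76e-07, and 0.000159, 1.44e-07 and 7.51e-08 adjusted over the list alone). Against the other genes of the 4 lists only, none of these 4 differences passed, and that of UV YUMM 1.1-9 did not pass at allele fractions of at least 20% (exact test, adjusted p = 0.0768; 4.05e-07 to 1 over the alternatives). In YUMM 1.3 the very long genes numbered 2 of 43 (exact test, adjusted p = 0.175, and 0.0243 adjusted over the list alone). With the lines pooled, 3 of 49 DNA repair genes, 3 of 28 melanoma genes, 4 of 27 bladder cancer genes and 5 of 41 receptor kinase and PI3K genes carried one (Fisher's exact test, adjusted p = 0.832, 0.261, 0.131 and 0.131). No other list and line passed, whether adjusted over all tests or over the list alone.

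The melanoma list had 2 of 28 members in YUMM 1.1 (exact test, adjusted p = 0.237, and 0.158 adjusted over the list alone). Gnaq A18G, in a G protein alpha subunit, had 6 of 28 reads, and Sf3b1 A2P, in a splicing factor, 7 of 30. Both are C>G changes, and sequence-dependent errors of this library remain a hypothesis for the C>G excess of YUMM 1.1. YUMM 1.1 also carried Rhoa C16Y, in a small GTPase, at 9:108327632 with 51 of 112 reads, or 45.5% (36.1 to 55.2), Flt4 K516T, in the VEGF receptor 3, at 26.3% and Ncor1 H1364R at 20.5%. MB49 carried Pik3ca N605Y, in the catalytic subunit of PI3K, at 3:32449975 with 24 of 51 reads, or 47.1% (32.9 to 61.5), and Erbb3 E926G, in a receptor of the EGFR family, at 10:128571701 with 24 of 42 reads, or 57.1% (41.0 to 72.3). Both belong to the bladder cancer list, of which MB49 had 2 of 27 members (exact test, adjusted p = 0.582). Its DNA repair variants were Mlh3 N291I, in a mismatch repair protein, at 71.4% and Rad50 Y666F, in the MRN break repair complex, at 32.1%. MB49 also carried Grin2a L717M, in an NMDA receptor subunit, at 48.5% and Kmt2a C1478F, in a histone H3 methyltransferase, at 39.5%. UV YUMM 1.1-9 carried Fbxw7 G348S, in a ubiquitin ligase subunit, with 9 of 53 reads, Chd7 G2126R with 6 of 32 and Chd6 M2541L with 9 of 44, both in chromatin remodellers, and Flt3 R490I, in a receptor kinase, with 3 of 32, beside Ntrk2 Q772*. YUMM 1.3 carried Rev3l F708V, in the catalytic subunit of DNA polymerase zeta, at 10% of 130 reads. The DNA repair list had 0 of 49 members with a protein change in UV YUMM 1.1-9, 0 in YUMM 1.1, 1 in YUMM 1.3 and 2 in MB49.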

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

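The common floor of 5 alternative reads and 10% and the use of the base columns were chosen after the data were seen; the other settings were fixed before. Over 456 alternative values of 58 results, 398 kept their direction and side of the threshold or stayed within the allowed range. Of the rest, 13 lost the threshold, 2 gained it, 32 left the allowed range and 11 changed direction. Some alternatives could not change a value, such as the common floor for the 3 single-line lists, which already met it. The C>T difference between UV YUMM 1.1-9 and YUMM 1.1 stayed between 19.5 and 22.0 percentage points under all 8 alternatives (exact test, highest adjusted p = 0.00127), and the difference in C>T after a pyrimidine between 39.2 and 52.8 under its 7 alternatives (highest adjusted p = 0.0117). The list sizes did depend on the allele fraction. With at least 20%, YUMM 1.1, UV YUMM 1.1-9 and YUMM 1.3 kept 278, 90 and 109 variants, of which 189, 63 and 77 changed the protein. Private variants then numbered 90 in UV YUMM 1.1-9 and 49 in YUMM 1.3, and the lists of UV YUMM 1.1-9 minus YUMM 1.1 differed by -188 variants and -126 protein-changing ones. With the common floor UV YUMM 1.1-9 kept 376 variants, all private, and 257 protein-changing ones, which puts it -52 and -42 from YUMM 1.1. The reversal at 20% follows from the removal of low allele fractions; the common floor sets a read count and an allele fraction together, and their parts were not tested apart. Median allele fractions at 20% or more rose by construction to 30.7%, 23.2%, 39.1% and 47.1% in YUMM 1.1, UV YUMM 1.1-9, YUMM 1.3 and MB49, and the UV YUMM 1.1-9 median was 15.5% with the common floor. Of the class and pair tests 7 passed at 20% or more, with fewer variants tested. Without multigene families YUMM 1.3 kept 135 variants and 103 protein-changing ones. Sites shared by YUMM 1.1 and YUMM 1.3, by YUMM 1.1 and MB49 and by YUMM 1.3 and MB49 numbered 48, 34 and 29 at 20% or more, 44, 11 and 8 without sites in 3 lists, and 41, 24 and 20 without multigene families. With the genes of any list as background, the excess of shared genes turned to -76.0 for YUMM 1.1 and MB49, -19.4 for YUMM 1.3 and MB49, and -113, -51.9 and -202 for UV YUMM 1.1-9 with YUMM 1.1, YUMM 1.3 and MB49, which follows from keeping only genes that some list holds. At 20% or more the excess for UV YUMM 1.1-9 was -0.899 with YUMM 1.1 and -0.314 with YUMM 1.3. The gene list tests past the threshold fell from 4 to 2 at 20% or more and to 0 with the background of listed genes. Known-variant identifiers, multi-base changes and coding lengths are not in the tables used here, so the alternatives that need them were not run. Depth limits single sites: 94 UV YUMM 1.1-9 variants rest on 3 alternative reads.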

Other observations

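The tests of this paragraph were chosen after the data were seen. For some chromosomes the share of variants differed from the share of protein-coding genes. That share counts genes and not coding bases, and the test takes neighbouring variants as independent. Gene length and clustering of variants can therefore enter these differences, and neither was taken into account. In UV YUMM 1.1-9, chromosome 2 held 81 of 653 variants, or 12.4%, where 8.14% of protein-coding genes lie (exact binomial test, adjusted p = 0.00307 over 84 tests), and chromosome 7 held 36, or 5.51% against 9.27% (adjusted p = 0.00463). Without multigene families both still passed (exact test, adjusted p = 0.0105 and 0.00226). YUMM 1.1 had 71 of 428 variants on chromosome 7, or 16.6% against 9.27% (exact test, adjusted p = 4.54e-05, and 0.0495 without multigene families). MB49 had 7 of 707 on chromosome X, or 0.990% against 4.41% (exact test, adjusted p = 1.29e-05, and 0.000220 without families). The lists hold no site at which nearly all reads carried the new base, so any such changes on X are absent from these counts. The other differences no longer passed without multigene families, with fewer variants tested. For chromosome 5 of YUMM 1.3, which had the lowest p of the 84 tests, the ratio of shares went from 2.91 to 1.60 (exact test, adjusted p = 2.79e-07 and 0.316), and for chromosome 5 of YUMM 1.1 from 2.02 to 1.08 (adjusted p = 7.46e-05 and 0.889). For chromosome 13 of YUMM 1.1 the ratio stayed near its size, at 0.247 and 0.258, on fewer variants (exact test, adjusted p = 0.00463 and 0.0664). The same held for chromosome X of YUMM 1.1, at 0.424 and 0.372 (exact test, adjusted p = 0.0366 and 0.110), and for chromosome 13 of YUMM 1.3, with 0 of 225 and 0 of 135 variants (adjusted p = 0.00378 and 0.0869). In UV YUMM 1.1-9 the median allele fraction was 19.1% for the 19 variants on X and 13.3% for the 631 on autosomes (permutation test, p = 0.00048), and 5 of the 19 lay in multigene families. The medians on X and on autosomes were 27.3% and 24.7% in YUMM 1.1, 28.1% and 18.7% in YUMM 1.3 and 26.8% and 45.8% in MB49, with 8, 8 and 7 variants on X, and these were not tested. Synonymous changes fell in the DNA repair gene Brca2 and the cohesin gene Stag2 in UV YUMM 1.1-9, and in Nlrc5, an activator of MHC class I genes, in YUMM 1.1; these genes were chosen after their values were seen.

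Tests chosen after the result was seen were the common floor for the low allele fraction, the share among the YUMM 1.1 variants themselves, the comparison past the first 300 coding bases and the base composition for the strand split; the others were written before. The additional variants of UV YUMM 1.1-9 had a median allele fraction of 13.5%, against 25% for the private variants of YUMM 1.1. With the same floor in both lists the medians still differed by -9.43 percentage points (bootstrap 95% interval -11.2 to -7.56), which argues against the lower read threshold as the whole cause. Sequencing errors would lack the sequence context of the list, yet C>T below the median allele fraction followed a pyrimidine in 89.0% (80.7 to 94.6), against 40% in YUMM 1.1. That covers only the 91 C>T changes with a known neighbour, out of 325 variants below the median. Errors among the other classes were not tested and stay open. The share of variants whose exact interval included the YUMM 1.1 private median was 60.5% (56.6 to 64.3), but among those YUMM 1.1 variants themselves it was only 72.2% (66.9 to 77.0), so that median is no fixed level of 1 mutated copy and the comparison excludes nothing. A mutated copy in every cell, a mutation carried by part of the cells and a higher copy number all stay open as hypotheses, since the sources used here hold no copy number.

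Where both neighbours were known, 25 of 31 C>G changes of YUMM 1.1 lay between G and C (80.6%), while neither neighbour differed from the other lists past the threshold (exact test, lowest adjusted p = 0.157). The first 300 coding bases held 20.4% of C>G and 19.7% of other changes, a difference of 0.711 percentage points (-7.51 to 10.6) that decided nothing, but past them the C>G share still exceeded that of MB49 by 17.4 percentage points (12.8 to 22.4). At sites of at least 60 reads the excess was 10.04 percentage points (5.42 to 15.2), so low depth could account for only part of it, and C>G lay less often in multigene families than the other changes, by -18.1 percentage points (-25.8 to -8.56). C>G sites were listed in another line in 12 of 98 cases, against 96 of 330 for other changes (Fisher's exact test, p = 0.000536). Sequence-dependent errors of this library and a mutational process of this line both remain as hypotheses.

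The T changes of MB49 and UV YUMM 1.1-9 split between strands in opposite ways, at 38.5% and 59.0% on the coding strand. T made up 48.5% of the A and T among unchanged codon bases (46.3 to 50.7), between the exact intervals of both lists, which argues against base composition as the whole cause. Among private variants outside multigene families the difference was 26.3 percentage points (17.7 to 34.4, Fisher's exact test, p = 4.54e-09). This argues against shared reads, as far as gene symbols mark such families. A candidate explanation is damage to different bases that is removed faster from the transcribed strand: pyrimidine damage would leave T on the coding strand, and adenine damage by a carcinogen would leave A there. It stays a hypothesis with little support on the UV YUMM 1.1-9 side, since that list did not differ from YUMM 1.1 past the threshold (9.27 percentage points, exact test, adjusted p = 0.0817), 53.2% (47.2 to 59.1) of its C>T changes had C on the coding strand, and gene expression was not analysed here.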
